A study of Drosophila melanogaster with 12 samples.

How the data were processed

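RNA from the heads of adult Drosophila melanogaster was measured on Affymetrix high-density oligonucleotide arrays, in which each gene is represented by a probe set of short oligonucleotides. The labels place the 12 arrays in 6 groups of 2, made of 3 lines (Canton S B, BG02514 and BG02257) and both sexes. Per the labels, the flies were reared side by side at 25 °C with 12 h of light and 70% humidity, and each sample pooled heads of 100 flies of 5 to 7 days of age. Both BG02257 male arrays carry replicate number 1 in their labels and are called BG02257 male 1a and 1b here. They were treated as separate samples, but the labels do not exclude that they are repeat arrays of 1 sample, and the numbers of arrays and degrees of freedom given rest on that choice.

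The deposited values are Signal intensities on a linear scale, made by the authors with the Signal metric of Affymetrix Microarray Suite 5.0, per the labels. The submitters' processing notes also name GCOS, whose version is not given in the sources used here, nor are background settings and detection calls. The deposited intensities had the same trimmed mean, 500.1, on all 12 arrays when 2% of each tail was left out, so each array had already been scaled. Global scaling of this kind assumes a like trimmed mean on every array. The trimming limits the pull of a few bright transcripts, but a change of many transcripts in one sex can still shift the others. A Signal is a relative intensity and gives no absolute amount of RNA.

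Of 14010 probe sets, 44 controls were left out. A platform annotation paired 12442 of the other 13966 probe sets with 1 gene symbol, 327 with several and 1197 with none, and 12393 were matched to a current record of the RefSeq gene table for the assembly Release 6 plus ISO1 MT. These cover 10843 genes, of which 1209 had more than 1 probe set. The deposited table names no genome build, so that assembly was used for gene names, chromosome arms and gene order only, and no coordinates are given. Probe sets with several symbols or none were tested and are not named. No probe set was paired with Tre1, which is therefore not analysed here.

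Each array was scaled to the same trimmed mean, which moved values slightly and no call of a named gene, and log2 of Signal was taken with no pseudocount. Probe sets with a mean Signal of at least 128.2, the 40th percentile, were tested. That left 8380 probe sets and 6778 genes, with 919 tested probe sets without a single gene name. All 12 arrays entered 1 model with 6 group means, equivalent to the model of line, sex and their interaction that the labels state. It was fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a variance trend), with 6 residual and 5.09 prior degrees of freedom, two-sided tests and Benjamini-Hochberg adjustment over the 8380 probe sets at 0.05. A difference called here is one with an adjusted p under 0.05 in this model. Averages over lines or sexes gave each group the same weight.

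For the sex effect and each pair of lines, the text names up to 10 genes per direction with the largest log2 change among called probe sets whose arrays did not overlap within any line (sex) or any sex (lines). It also names members of gene lists past the threshold, and the measured neighbours of Tre1 and Gr5a, 5 on either side. Where a gene had several probe sets, the brightest stood for it. The lists, this rule, the design and 14 other settings were fixed before the data were examined. In 30 lists at least 5 genes were tested, and these were tested with camera (limma) at a preset correlation of 0.01, again with an estimated correlation, and with fry. The fry test asks whether the genes of a list move one way on balance, and does not compare them with other genes. Its mixed form, called mixed fry here, asks whether they change in either direction, again without comparing them with other genes. Positions of called genes on chromosome arms were compared with two-sided Fisher's exact tests. A window of 100 genes on either side of Tre1 in gene order replaced a window in base pairs, which would have needed coordinates. The 3'/5' ratios of control probe sets, a sign of RNA integrity, were compared with exact permutation tests.

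The model was tested on simulated arrays with the real means and the spreads that limma estimated by sharing information between probe sets. Probe sets were drawn independently of each other. In each comparison tested there were 8380 probe sets, of which 100 were changed by 1 and 100 by 2 on the log2 scale. For the sex effect it recovered 83% of changes of 1 and 99% of changes of 2, with 12 false calls (6.19% of calls). For BG02514 against Canton S B it recovered 72% and 98%, with 7 false calls (3.95%). In simulated lists of 20 genes among 6778, a shift of 0.5 gave a camera adjusted p of 3.22e-22 at the preset and 0.00101 at the estimated correlation. None of the unchanged lists was called (0 with either). As these genes were drawn independently, the lists do not show how camera behaves when genes of a list vary together. In the real data the estimated correlation was 0.34 for the ribosomal protein list and 0.54 for the muscle list. These 2 arrays per group set the precision: the median standard error was 0.16 for the sex effect and 0.20 for a pair of lines, on the log2 scale.

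The other settings were quantile normalization, values as deposited, median centring, no filter, a filter at the 60th percentile (mean Signal 300.7), a pseudocount of 14.7, no variance trend, the replicate number as a block, the two-way model fitted to each probe set alone on log2 and on linear Signal, only the groups compared, both BG02257 male arrays left out, and, for lists, an estimated correlation and the mean of a gene's probe sets. Each of the 12 arrays was also left out in turn, which leaves a group with 1 array whose spread is taken to be that of the other groups. After seeing the data 2 settings were added, the list tests without BG02257 male 1a and the 3'/5' ratio of the GAPDH control as a covariate. Of 12 tests of explanations, 7 were set before their result was seen and 5 after. A test of scaling for the ribosomal protein genes was replaced after its result was seen, and both results are given. Genes outside the naming rule were chosen after their values were seen and are marked so. Plots were drawn with matplotlib 3.10.9.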

Results

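Head RNA of 3 lines of Drosophila melanogaster was compared on 12 arrays, 2 for each sex of each line. Canton S B is a wild-type strain and was taken as the common background line of the comparisons. BG02514 and BG02257 belong to a collection of lines that each carry a P{GT1} gene-trap transposon. How alike the lines are outside their insertions was not tested. Their insertion sites are not given in the sources used here. The series title names the region of Tre1, a G protein-coupled receptor needed for germ cell migration, and Gr5a, a taste receptor for trehalose. The design asks which transcripts differ between lines, between sexes, and between sexes in a line-dependent way. Median Signal ranged from 182.9 to 206.1 between arrays. Replicates correlated at Spearman's rho of 0.942 (BG02257 males) to 0.964 (BG02514 females) across probe sets, which are not independent replicates. The median correlation of an array with arrays of other groups was 0.942 to 0.955. Replicates were thus little or no closer to each other than to arrays of other groups. The number of arrays, 2 per group, limits the precision of every comparison.

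Females had far more yolk protein RNA in their heads than males in all 3 lines. Signal of Yp1 was 85212 ± 9069 in females and 1405 ± 2619 in males (SD, n = 6 each), a log2 difference of 7.33 ± 0.58 (SE, limma adjusted p = 7.44e-05). Yp2 and Yp3 rose by 7.29 ± 0.42 (adjusted p = 4.59e-06) and 5.31 ± 0.22 (adjusted p = 2.91e-07). The male mean of Yp1 was raised by BG02257 male 1a, with a Signal of 6747.4 against 171.7 to 496.1 in the other 5 male arrays. Ndg, which encodes the basement membrane protein nidogen, was higher in females by 3.91 ± 0.33 (adjusted p = 9.57e-05), and dsx, the transcription factor at the end of the sex determination cascade, by 3.75 ± 0.48 (adjusted p = 0.00311). Male Signals of Ndg (21.8 ± 5.51, SD, n = 6) and dsx (24.6 ± 21.9) were close to background, so the size of these 2 differences is uncertain, and a pseudocount of 14.7 gave 3.20 and 2.95. No other probe set of dsx was tested, so its value is that of a single probe set and need not hold for all dsx transcripts. The secreted fat body factor fit was higher by 3.31, Obp99a by 3.11, rost, a gene of myoblast fusion, by 2.98, the chitinase Cht2 by 2.72 and the T-box factor org-1 by 2.14.

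Males had more RNA of Obp99b, an odorant-binding protein, with a Signal of 2431 ± 1251 against 111 ± 64.1 in females (SD, n = 6 each), a log2 difference of −4.48 ± 0.36 (SE, adjusted p = 8.23e-05). The cytochrome P450 gene Cyp4d21 was also lower in females (−3.26 ± 0.24 on the log2 scale, adjusted p = 4.53e-05), and sxe2, a lipase-like gene, differed by −2.93 ± 0.11 (adjusted p = 1.05e-07). Smaller differences in the same direction were those of CG13670 (−2.11), Cyp313a1 (−1.78), the sorbitol dehydrogenase Sodh1 (−1.66), Cyp309a1 (−1.54), Npc2h (−1.43), of the sterol-binding NPC2 family, the nuclear pore gene Aladin (−1.41) and CG7997 (−1.24). In all, 238 of 8380 probe sets were called between the sexes, 164 higher and 74 lower in females, against 1259 at an unadjusted level of 0.05 where 419 were expected by chance. They included 182 named genes, and 55 had no single name. Quantile normalization called 98 higher and 78 lower. Leaving out BG02514 female 1, female 2, male 1 or male 2 gave 132, 116, 138 and 134 calls, and leaving out BG02257 female 1 or female 2 gave 148 and 128. Of the 20 genes named here, 17 kept their call without any 1 array; CG13670, Sodh1 and Cyp309a1 lost theirs in some of these fits.

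**Figure D1:**
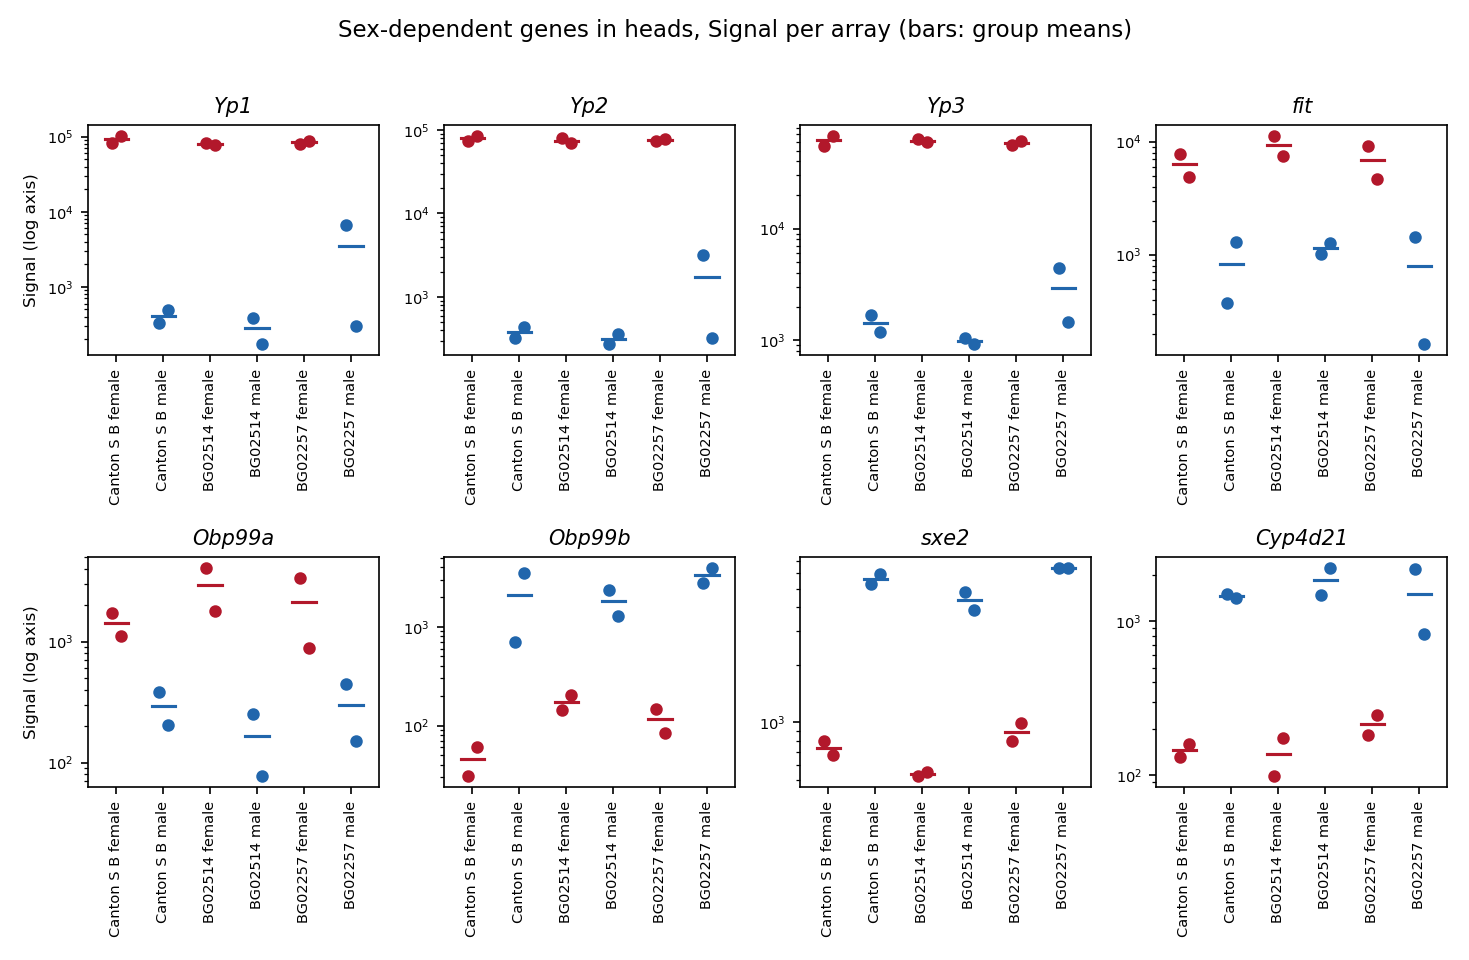
Signal of 8 genes with a sex difference on a log axis, for each of the 12 arrays (points) by line and sex, with horizontal bars at group means. Yp1, Yp2, Yp3, fit and Obp99a lie higher in females and Obp99b, sxe2 and Cyp4d21 higher in males, and BG02257 male 1a stands above the other male arrays in Yp1 at 6747.4.

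All 7 measured genes of the sex-responsive head fat body were called, 4 higher (Yp1, Yp2, Yp3 and fit) and 3 lower in females (Obp99b, Cyp4d21 and sxe2). These genes are known for sex-dependent expression in head fat body. As the list holds genes of both directions, a test for movement one way does not decide whether they differ (camera, adjusted p = 0.5). All 7 were called when adjusted over the list alone. Of 24 tested odorant-binding protein genes, 4 were higher in females, Obp99a, Obp56e (2.04), Obp56d (0.85) and Obp19a (0.66), and Obp99b was lower. Adjusted over the list alone 12 of the 24 were called, and as a list they showed no common direction (adjusted p = 0.736). Among 52 cytochrome P450 genes, Cyp18a1, an ecdysone-inactivating enzyme, was higher in females (1.02), and Cyp4d21, Cyp313a1, Cyp309a1 and Cyp4d2 (−0.54) were lower; 6 were called when adjusted over the list alone, and camera gave an adjusted p of 0.271. In the list of sex determination and dosage compensation, dsx and Sxl (0.84), the switch gene of the cascade, were higher in females among 13 tested genes, which were also the 2 called when adjusted over the list alone (camera, adjusted p = 0.654). Drs, which encodes the antifungal peptide drosomycin, was lower in females (−1.12), as were the glutathione S-transferases GstE9 (−1.10) and GstS1 (−0.62), the chaperone Hsp60A (−0.45), the glycolytic enzyme Pgi (−0.45) and Npc2g (−0.39). Higher in females were Ugt49C1 (0.52) and the cuticle protein genes Cpr64Ac (1.54) and Cpr67B (0.61). Of these list members, several lost their call in some of the 12 fits that left out 1 array: Hsp60A in 11, Cpr64Ac in 10, Npc2g and Ugt49C1 in 9, Cpr67B in 8, Pgi and GstS1 in 7, Sxl and Cyp4d2 in 5 and Drs in 1.

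Cytosolic ribosomal protein genes were higher in female heads as a group. Of 31 tested members, 21 rose and 10 did not pass the test, with a median log2 difference of 0.38; adjusted over the list alone 28 were called. The largest differences were those of RpL37A (0.69), RpS12 (0.67), RpS27A (0.60) and RpLP1 (0.56). In Canton S B, BG02514 and BG02257 the difference was 1.14, 0.80 and 0.14 for RpL37A, whose arrays overlapped between the sexes in some line. RpS12 gave 0.85, 0.73 and 0.43, RpS27A 0.97, 0.47 and 0.36, and RpLP1 0.74, 0.56 and 0.37. All 21 called members differed least in BG02257, but no probe set passed the test for a sex difference that depended on line. The camera test gave an adjusted p of 4.94e-26, and adjusted p = 0.294 with an estimated correlation, so the call does not hold with that setting, while fry gave an adjusted p of 0.00614. With quantile normalization the median was 0.11, 25 of 31 members were above 0, RpL17 turned to −0.01 and 3 were called. Leaving out BG02514 female 1, female 2, male 1 or male 2 left 13, 8, 11 and 10 members called, and leaving out BG02257 female 2 or Canton S B male 1 left 8 and 12.

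**Figure D2:**
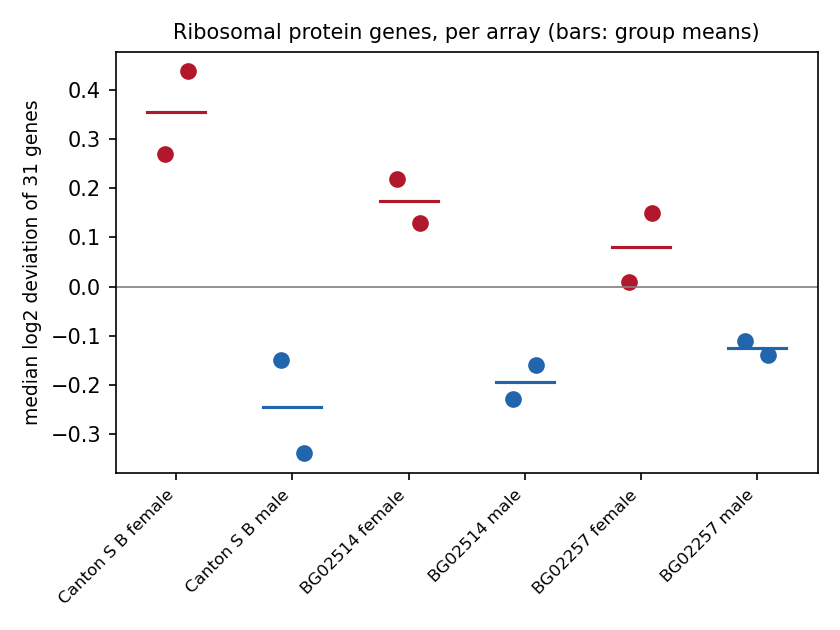
Median log2 deviation of 31 ribosomal protein genes from each gene's mean over all arrays, for each of the 12 arrays (points) by line and sex, with horizontal bars at group means. All 6 female arrays lie at 0.01 or above and all 6 male arrays at −0.11 or below, on values scaled to a common trimmed mean; with quantile normalization the median female minus male difference was 0.11 and 1 gene named here, RpL17, turned to −0.01.

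Marker lists of other tissues also differed between the sexes. The hemocyte list lay higher in females, with 11 of 11 tested members above 0 and a median of 0.33, although no single member was called over all probe sets and 3 when adjusted over the list alone (adjusted p = 0.00573, and adjusted p = 0.732 with an estimated correlation). The muscle list lay higher as well, with 11 of 12 members above 0, a median of 0.30, no member called over all probe sets and 4 when adjusted over the list alone (adjusted p = 0.00573, and adjusted p = 0.767 with an estimated correlation). Genes of testis and accessory gland lay lower, with 7 of 8 members below 0 and a median of −0.32 (camera, adjusted p = 0.0363, and adjusted p = 0.428 with an estimated correlation). Of these, alphaTub84D (−0.62), an alpha-tubulin gene, was called, and another of its probe sets gave −0.28. Only 8 of the 46 members on the array passed the brightness filter, so the list describes members detected in heads and does not show RNA of those tissues. Genes of ovary and egg did not differ by this test, with a median of −0.08 over 8 tested members (adjusted p = 0.542). Without BG02257 male 1a the adjusted p was 0.00246 for hemocytes, 1.38e-05 for muscle and 0.0757 for testis and accessory gland, whose median was then −0.33, so that the last list was no longer called at a like size. The lists of the mitochondrial respiratory chain (median then 0.08) and of the sex-responsive head fat body were called without that array and not with it. For the head fat body list, with genes of both directions, neither outcome shows whether its genes differ between the sexes. The mitochondrial list had a median of −0.10 with quantile normalization (camera, adjusted p = 0.0224).

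The other lists did not pass the camera test between the sexes. They were those of chemosensory proteins, chemotaxis and G protein signalling, the circadian clock, cuticle proteins, cuticular hydrocarbon synthesis, gut digestive enzymes, eye pigment, fat body and lipid metabolism, glia, glutathione S-transferases, heat shock proteins, immune effectors, insulin signalling, the mitochondrial respiratory chain, neuronal and synaptic genes, neuropeptides, odorant receptors, oxidative stress defence, phototransduction, sugar metabolism and UDP-glycosyltransferases. With the head fat body, odorant-binding protein, cytochrome P450, sex determination and ovary lists they make 26 lists with adjusted p from 0.0863 to 0.818. In short lists, the gustatory receptors Gr8a (0.22) and Gr98d (0.08) and the stress gene TotE (0.50) were not called between the sexes. The fry test called 5 lists in one direction, ribosomal proteins and, each at an adjusted p of 0.0452, glia, chemotaxis and G protein signalling, cuticular hydrocarbon synthesis, and testis and accessory gland. For changes in either direction, mixed fry called 16 lists. Among them were those of cytochrome P450 (adjusted p = 3.25e-09), sex determination (1.9e-07), head fat body (3.88e-07), odorant-binding proteins (2.46e-06), glutathione S-transferases (0.000205) and glia (0.000267). With quantile normalization glutathione S-transferase genes were called as lower in females (median −0.11, adjusted p = 0.0444). With an estimated correlation camera called 0 of the 30 lists in each of the 4 comparisons, the smallest adjusted p being 0.294 between the sexes.

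Within single lines, sex differences were called at 34 probe sets in Canton S B, 10 in BG02514 and 12 in BG02257, and whether these differ is a matter of the interaction test. No probe set passed the limma test for a sex difference that depended on line (0 of 8380 called, 235 at an unadjusted level of 0.05 where 419 were expected by chance). The two-way model fitted to each probe set alone also called 0, with 278 at that level on log2 Signal and 310 on linear Signal. The largest F was that of Npc2g (20.7, adjusted p = 1), whose female minus male difference was −0.09 in Canton S B, 0.10 in BG02514 and −1.18 in BG02257. Interaction calls appeared when BG02257 male 1b was left out. In that fit BG02257 males are represented by male 1a alone, the array with raised yolk protein Signals. Genes of the X chromosome were called between the sexes more often than others, 46 of 1171 against 2.33% elsewhere (3.93%, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0161 over 5 arms). On the X 30 were higher and 16 lower in females, and on the other arms 79 and 50 (Fisher's exact p = 0.724).

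BG02514 heads differed from Canton S B in a small set of genes. CG32523 was higher by 2.53 ± 0.23 on the log2 scale (SE, adjusted p = 0.00114), with a Signal of 3363 ± 1376 against 581 ± 225 (SD, n = 4 each). The photoreceptor adhesion protein gene chp was higher by 1.79, Iml1, of the GATOR1 complex, by 1.40, the transporter gene MFS10 by 1.29 and the aminopeptidase gene Psa by 1.03. The serine protease gene teq was higher by 1.90 at its brightest probe set and by 2.61 at another, while its remaining probe set went the other way at −1.20 (adjusted p = 0.00106). Lower in BG02514 were se (−1.43 ± 0.16, adjusted p = 0.00355), needed for the red eye pigment drosopterin, udd (−1.19), a gene of ribosomal RNA transcription, Ctr9 (−1.14), of the Paf1 complex, inaD (−0.85), the scaffold of phototransduction, and sturkopf (−0.83), which encodes a lipid droplet protein. In all 15 probe sets were called, 8 higher and 7 lower, with 672 at an unadjusted level of 0.05 against 419 expected. With only the groups compared in the model, 17 were called, 14 higher and 3 lower. Leaving out BG02514 female 1, female 2, male 1 or male 2 gave 6, 4, 4 and 5 calls and leaving out Canton S B female 2 or male 2 gave 7 and 6. Of the 11 genes named, CG32523, teq and se kept their call without any 1 array and 8 did not.

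Gut digestive enzyme genes, markers of another tissue, were higher in BG02514 than in Canton S B as a list, with 22 of 23 members above 0 and a median of 0.34, though no single member was called over all probe sets or when adjusted over the list alone, 0 in both (camera, adjusted p = 4.92e-06, and adjusted p = 0.25 with an estimated correlation). Genes of chemotaxis and G protein signalling were higher as a list, with 9 of 10 members above 0, a median of 0.23 and 0 called when adjusted over the list alone (camera, adjusted p = 0.0247, and adjusted p = 0.25 with an estimated correlation). Theirs was the 1 list that fry called in one direction (adjusted p = 0.0389). Among 14 eye pigment genes and 13 phototransduction genes, se and inaD were the members called, both lower, with 1 called in each list when adjusted over the list alone. The other 28 lists, these among them, gave camera adjusted p from 0.0827 to 0.993. Those with the most calls adjusted over the list alone were odorant-binding proteins (6 of 24), immune effectors (6 of 14) and other chemosensory proteins (3 of 5). None of their members was called over all probe sets. Mixed fry called 5 lists, odorant-binding proteins (adjusted p = 0.000237), phototransduction (0.000311), eye pigment (0.000412), glia (0.00192) and immune effectors (0.00948).

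In the comparison of BG02257 with Canton S B, chp was again higher (1.73 ± 0.23, SE, adjusted p = 0.0251) and se again lower (−1.18 ± 0.16, adjusted p = 0.0251). CG11899 was lower (−1.98 ± 0.20 on the log2 scale, adjusted p = 0.00314), with a Signal of 614 ± 126 against 2499 ± 965 (SD, n = 4 each). Also lower were stops (−1.12), a photoreceptor gene, Npc2g (−1.08) and ScsbetaG (−0.94), a subunit of succinyl-CoA synthetase. In all 8 probe sets were called, 1 higher and 7 lower, with 338 at an unadjusted level of 0.05, fewer than the 419 expected by chance. Leaving out BG02257 male 1b gave 24 calls, Canton S B female 2 gave 12, and leaving out BG02257 male 1a, BG02257 female 1, or any of the 4 BG02514 arrays gave 2. It was 4 without BG02257 female 2, Canton S B female 1 or Canton S B male 2. CG11899 and Npc2g kept their call without any 1 array, and the other 4 of the 6 named genes did not.

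Of the lists, 5 were called between BG02257 and Canton S B, none of them with an estimated correlation. Cytochrome P450 genes lay higher (37 of 52 above 0, median 0.06, 0 called over the list alone, adjusted p = 0.0112), as did odorant-binding protein genes (19 of 24, median 0.12, 1 called over the list alone, adjusted p = 0.00636) and the head fat body genes (6 of 7, median 0.38, 0 called over the list alone, adjusted p = 0.0112). The last list holds the yolk proteins that were raised in BG02257 male 1a. Eye pigment genes lay lower (10 of 14 below 0, median −0.19, se the 1 called over the list alone, adjusted p = 0.0112), and so did ribosomal protein genes (29 of 31, median −0.07, 1 called over the list alone, adjusted p = 0.00824). With an estimated correlation the adjusted p was 0.942 for ribosomal proteins and 0.667 for the other 4, and with quantile normalization the ribosomal protein list was not called (median −0.02, adjusted p = 0.178). The remaining 25 lists gave adjusted p from 0.131 to 0.984.

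Between the 2 insertion lines, CG7607 was 2.94 ± 0.28 higher in BG02514 on the log2 scale (SE, adjusted p = 0.00171), with a Signal of 1705 ± 284 against 223 ± 42.7 in BG02257 (SD, n = 4 each). MFS10 (1.68), CG32523 (1.67), CG11899 (1.63), Iml1 (1.55), the anion exchanger gene Ae2 (1.33), Npc2g (1.26), CG14567 (1.20), Psa (1.16) and CG10680 (0.80) were also higher in BG02514. Lower there were udd (−1.42), Ctr9 (−1.26), Acat2 (−1.23), CG3566 (−1.13), Hk (−1.05), a subunit of the Shaker potassium channel, sturkopf (−0.98), the photoreceptor gene Culd (−0.83), the olfactory gene Os-C (−0.78) and NaPi-III (−0.66). A dimmer probe set of Hk gave 0.20 and was not called. In all 28 probe sets were called, 15 higher and 13 lower in BG02514, with 840 at an unadjusted level of 0.05. Leaving out BG02257 male 1b gave 90 calls, male 1a 14, female 1 2 and female 2 13, and leaving out BG02514 female 1, female 2, male 1 or male 2 gave 9, 2, 3 and 2. CG7607 and Npc2g kept their call without any 1 array, and 17 of the 19 named genes did not.

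Between the insertion lines, gut digestive enzyme genes were higher in BG02514 as a list (18 of 23 above 0, median 0.41, camera, adjusted p = 0.000476). The 1 member called, over all probe sets or over the list alone, was Npc2g. Like Npc2h it is of the NPC2 family and not a digestive enzyme, so no digestive enzyme gene was called. Fat body and lipid metabolism (15 of 17, median 0.19, 1 called over the list alone) and neuronal and synaptic genes (14 of 16, median 0.18, 0 called over the list alone) were also higher in BG02514 as lists, each with a camera adjusted p of 0.00744. Odorant-binding protein genes were lower (20 of 24 below 0, median −0.28, 4 called over the list alone, adjusted p = 0.000476). With an estimated correlation the adjusted p was 0.544 for odorant-binding proteins and 0.519 for the other 3. The remaining 26 lists gave adjusted p from 0.0914 to 0.984.

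**Figure D3:**
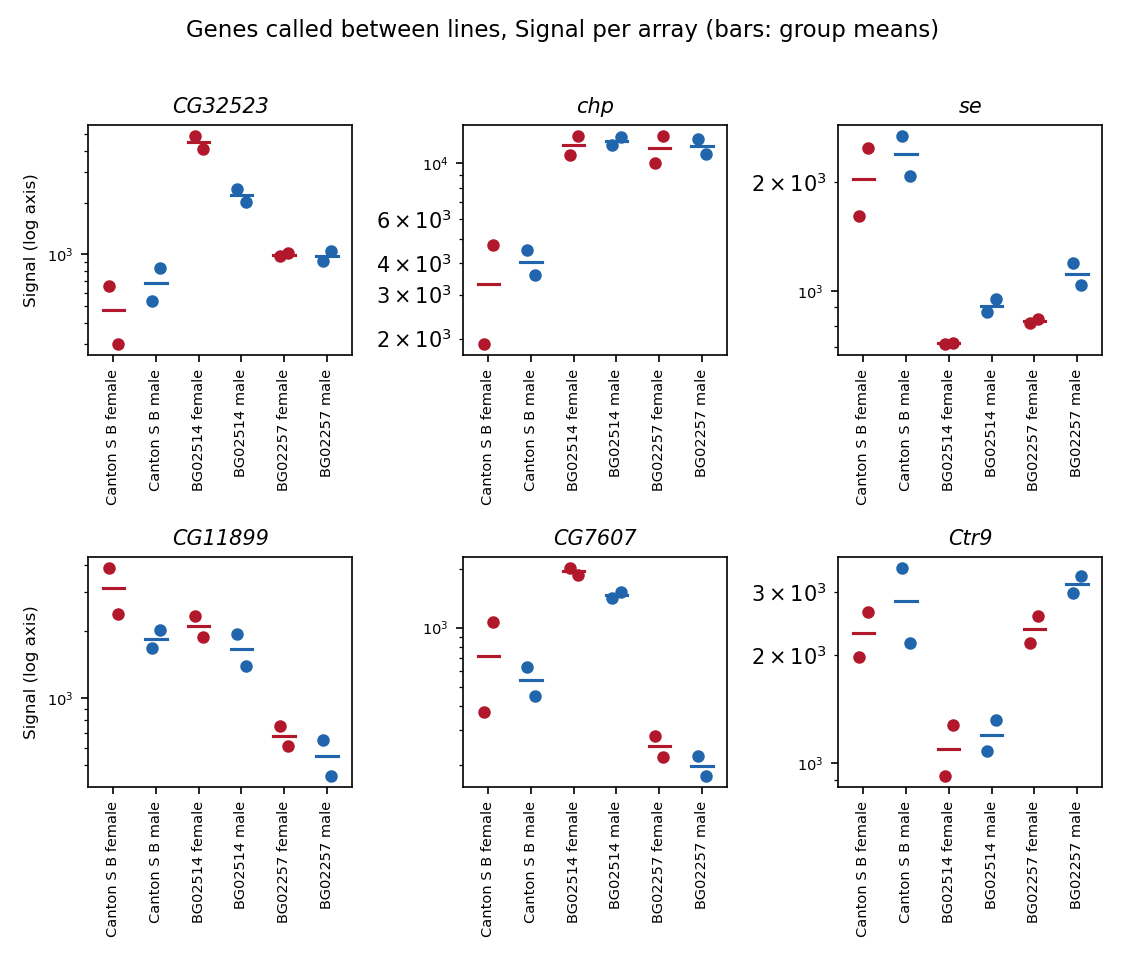
Signal of 6 genes called between lines on a log axis, for each of the 12 arrays (points) by line and sex, with horizontal bars at group means. Both insertion lines lie above Canton S B in chp and below it in se, CG32523 is highest in BG02514, CG11899 is lowest in BG02257, CG7607 is lowest in BG02257 and Ctr9 lowest in BG02514.

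Any difference among the 3 lines was called at 35 probe sets (limma F test, 699 at an unadjusted level of 0.05 against 419 expected). This count was 8 without BG02514 female 2, 11 without BG02514 female 1, 7 without either BG02514 male array, 19 and 22 without BG02257 female 1 and 2, 22 and 57 without BG02257 male 1a and 1b, and 21 without Canton S B male 2. Within one sex the calls were few. In females there were 3 between BG02514 and Canton S B, 2 between BG02257 and Canton S B and 2 between the insertion lines. In males there was 1 between BG02514 and Canton S B, and limma called 0 in the other 2 comparisons, with 361 and 611 at an unadjusted level of 0.05. The 2 comparisons with Canton S B share its 4 arrays. Their log2 changes correlated at 0.35 across probe sets, below the 0.50 (0.47 to 0.54 in 100 simulations) of unchanged groups against shared controls, with a covariance of 0.031 in both cases. With the Canton S B arrays split between them the correlation was 0.05 or −0.10. Called in both were chp (higher), se and the teq probe set that went down (−1.20 and −0.72), that is 1 higher and 2 lower against 0.001 and 0.006 expected of independent lists, which these are not, as they share controls.

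None of the measured genes of the Tre1 and Gr5a region was called between lines. Gr5a gave Signals of 34.9 and 36.2 in Canton S B females, 137.6 and 43.6 in Canton S B males, 53.8 and 64.7 in BG02514 females, 64.3 and 115.3 in BG02514 males, 56.7 and 87.4 in BG02257 females and 158.9 and 288.6 in BG02257 males. Its mean was below the brightness filter, so its test is given for information. The log2 difference was 1.23 ± 0.43 (SE) between BG02257 and Canton S B (limma adjusted p = 0.905) and 0.44 ± 0.43 between BG02514 and Canton S B (adjusted p = 0.916). Without Canton S B male 2 these were 0.81 and 0.03, and without Canton S B male 1 they were 1.64 and 0.86. Of Gr5a and its 10 measured neighbours in gene order, 9 were tested and 0 were called between lines with limma. Of these 9, only 1 passed an unadjusted level of 0.05 between any lines, AdamTS-B, a secreted metalloprotease gene, at −1.05 in BG02514 against Canton S B (adjusted p = 0.269, and 0.0384 adjusted over the list alone) and −1.03 against BG02257 (adjusted p = 0.241, and 0.043 adjusted over the list alone). Gr5a, below the filter, also passed that level between BG02257 and Canton S B (0.17 adjusted over the list alone), with arrays that did not overlap within either sex. The neighbours OtopLa, OtopLc, Sirt4, CG4119, Rab18, PGAP1, cv, CG3149 and CG42449 lay between −0.47 (CG4119 in BG02257) and 0.56 (PGAP1 in BG02514) against Canton S B. Within 100 genes on either side of Tre1, 105 genes were tested and CG3566 was the 1 called between any lines, namely between the insertion lines (Fisher's exact p = 0.291 against genes elsewhere).

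Genes called in BG02514 lay on chromosome arm 3L more often than elsewhere. Against Canton S B these were 6 of 1282 tested genes on 3L (0.468% against 0.092% elsewhere, Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0459 over 5 arms), and against BG02257 10 of 1282 (0.78% against 0.221%, adjusted p = 0.0214). A run of 13 neighbouring tested genes on that arm held Acat2, Ctr9 and sturkopf, lower in BG02514, and Psa and Iml1, higher there. Acat2 was not called against Canton S B (−1.05 ± 0.20, SE, adjusted p = 0.0993). The Fisher tests take genes as independent, but the other genes of this run entered the arm count against Canton S B, and all 5 that against BG02257. The arm counts and the run are thus not separate findings. Both comparisons also share the BG02514 arrays. Of these 5 genes none was called without BG02514 female 2, male 1 or male 2, and 3 were called without BG02514 female 1, BG02257 female 1, BG02257 female 2 or BG02257 male 1a. Their differences from BG02257 stayed at −0.89 (sturkopf) or below and at 1.10 (Psa) or above in all 12 fits that left out 1 array. Between them lay Nt5a, Herc4, ND-ACP, indra, Ptp61F, CG12084, hfp and cue, none of which was called in either comparison.

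**Figure D4:**
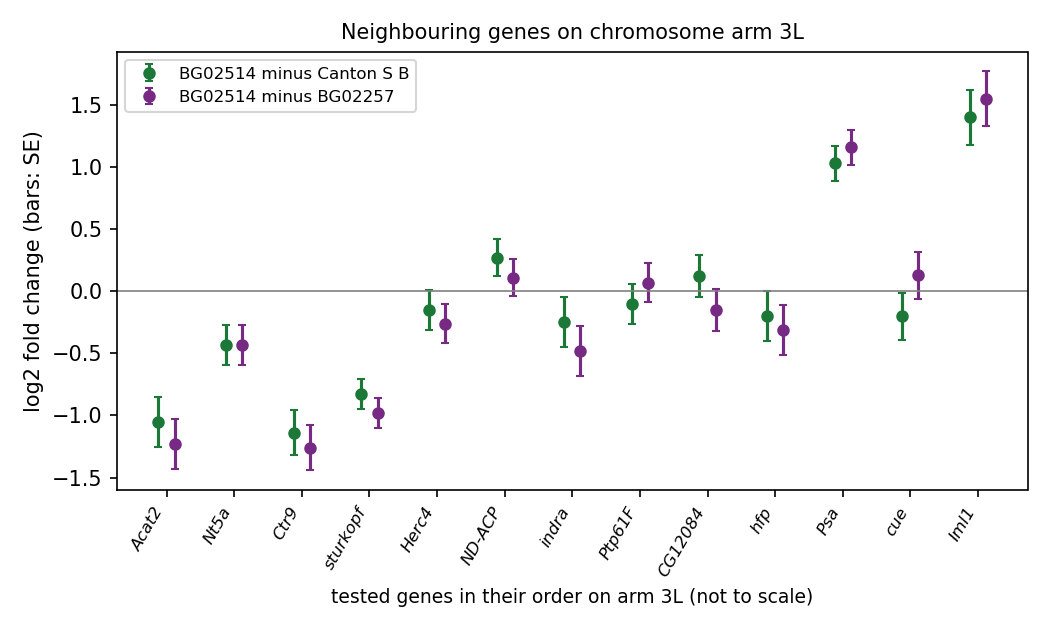
Log2 fold change of 13 neighbouring tested genes on chromosome arm 3L in BG02514, against Canton S B (green) and against BG02257 (purple), in gene order and not to scale, with bars of 1 standard error. Acat2, Ctr9 and sturkopf lie at −0.83 or below, Psa and Iml1 at 1.03 or above, and the genes between them within −0.48 and 0.27.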

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

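The tests of both explanations for BG02257 male 1a, of chance positions on 3L, of scaling and of ovary RNA were chosen after the results were seen, and the other tests here before.

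Yolk protein Signals in BG02257 male 1a lay far above those of the other 5 male arrays. Values here are Signals, while each gap was taken on log2 Signal as a share of the range of the arrays compared. Yp1 was 6747.4 against 171.7 to 496.1, with a gap of 0.711 of the log2 range of the male arrays. Yp2 was 3187.6 against 271.1 to 437.2, with a gap of 0.806. In BG02514 female 2, udd was lower (510.5 against 715.4 to 751.4 in the other BG02514 arrays, gap 0.872), and in BG02514 female 1, sturkopf was higher (1266.6 against 981.7 to 995.5, gap 0.943). BG02257 male 1a had less Ae2 (357.9 against 570.5 to 590.9 in the other BG02257 arrays, gap 0.928) and more CG14567 (911.1 against 694.2 to 727.6, gap 0.831). Gr5a in Canton S B male 1 was 137.6 against 34.9 to 43.6 (gap 0.838). These gaps passed Dixon's test in 7 of 111 groups of arrays, where a rate of 1 in 20 groups would give 5.6. That rate holds for independent groups of like arrays. The groups here mix lines or sexes and share arrays, so the count does not decide whether chance gave these gaps.

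The yolk proteins in BG02257 male 1a may come from female RNA in the sample, of which the levels of Yp1, Yp2 and Yp3 would need shares of 7.55%, 3.72% and 5.33%. Of 8 other genes at least 4-fold higher in females, dsx, Obp56e, Cht2, Obp99a and fit gave shares of 21.2%, 20.9%, 20.5%, 11.8% and 9.12%, and rost, Ndg and org-1 gave −1.59%, −1.9% and −19.2%. Their median, 10.4%, lay above those of the other male arrays (−5.83% to 5.16%), but the genes scatter widely and the median is close to the upper bound set for it. An array of a female sample with a male label is argued against by Yp1, which was 11.5 times higher in the lowest female array. No biological explanation was tested.

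Genes called in BG02514 lay close together on chromosome arm 3L, where Acat2, Ctr9, sturkopf, Psa and Iml1 each had another called gene within 5 tested genes. Chance positions stay open: of 10000 random orders a share of 0.0096 held as many as 5 of 26 called genes near another, but the window was chosen after the pattern was seen, and the share was 0.0958 with a window of 1 tested gene, 7e-04 with 2, 0.0025 with 3, 0.0113 with 10, 0.0259 with 20 and 0.0635 with 50. With 1 array left out it was 5e-04, 0.0017 and 0.0066 without Canton S B male 1, female 2 and female 1, 0.0138 and 0.0245 without BG02257 male 1a and 1b, 0.0853 without Canton S B male 2, 0.0923 without BG02514 female 1 and 0.141 and 0.182 without BG02257 female 1 and 2, while without BG02514 female 2, male 1 or male 2 only 5 or 6 genes were called, none of these 5 among them, and the share says nothing. Sequence differences under single probe sets and differences in RNA level cannot be told apart here, since none of these 5 genes had another tested probe set, and the 33.3% of 18 cases in which other probe sets went the same way come from 4 other genes. A difference of the lines themselves stays open and untested.

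Ribosomal protein genes were higher in females with a median of 0.38 (SD over genes 0.17). A shift of all bright probe sets is argued against by other genes of like Signal, with a median of 0.00, while random sets of such genes reached 0.08 at the upper end of their 95% range. Ovary RNA stays open: 28 ovary genes had a median of −0.08, but 20 of them lay under the brightness filter, and the 8 over it include genes expressed beyond the ovary, such as Cp190. Scaling stays open as well: quantile normalization took the median to 0.11 (SD 0.19) and the calls from 21 to 3, a result that went with scaling as the explanation under the test first set, and a second test, chosen only after that result, gave a difference of 0.24 from genes of like Signal, which lies between its bounds. Ribosomal protein genes make up 21 of the 100 brightest probe sets, which quantile normalization forces to a common distribution, and a sex difference in these genes stays open beside these.

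Other splits of the arrays were counted with a model of line and sex alone, so the real counts differ from those of the 6 group means. Chance is argued against for the sexes, where the real split gave 297 calls against at most 9 in another, the only 1 of 100 as large. For BG02514 and Canton S B (25 against 0) and for BG02514 and BG02257 (44 against 1), the real split was the only 1 of 34 as large. With 34 splits no smaller share was possible, and the tests were not adjusted for their number, so chance was not excluded for these pairs. Chance was not excluded for BG02257 and Canton S B, where the real split gave 1 call and the highest other split 55, with 3 of 34 as large. That split set BG02257 male 1a, BG02257 female 1, Canton S B female 2 and Canton S B male 1 against the rest. It was picked as the highest of many splits. Whether its count reflects a structure of the arrays beyond line and sex was not tested. The GAPDH 3'/5' ratio was 3.71 and 3.70 in these Canton S B arrays and 6.16 and 5.89 in the other Canton S B arrays, while the BG02257 arrays had 4.79 and 4.14 on this side and 4.59 and 4.98 on the other. RNA integrity was not tested as the source of the split. For the 3 lines, 2 of 100 splits gave as many. The highest other split gave 162 calls against 45, so chance was not excluded there, and a structure of the arrays was again not tested.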

How the results depend on the processing

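The list tests without BG02257 male 1a and the GAPDH covariate were chosen after seeing the data, and the other settings before. Among values of named genes, 1982 of 2782 kept their direction and side of the threshold, 799 lost their call and 1 reversed. The causes were not tested unless stated.

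Values as deposited gave the same counts and the same calls of named genes, since the arrays had been scaled already, with small shifts in single values. With the pseudocount and the stricter filter all named values tested kept their call. Quantile normalization left 21 calls by line and 3 ribosomal protein genes, and RpL17 reversed to −0.01. No filter left 145 sex calls, 9 ribosomal protein genes and 2 lists between BG02257 and Canton S B, with more probe sets tested. No variance trend left 100 sex calls, 13 by line, 5 between BG02514 and Canton S B, 1 between BG02257 and Canton S B, 9 between the insertion lines and 3 ribosomal protein genes. The replicate number as a block left 16 by line, 2 between BG02257 and Canton S B and 16 between the insertion lines. Replicate numbers did not pair the arrays, as deviations of equal numbers correlated at −0.24 to 0.27 over 10 pairs of groups.

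The two-way model fitted to each probe set alone, which shares no information between probe sets, called 108 on log2 Signal for sex, 1 by line, 1 between BG02514 and Canton S B, 1 between BG02257 and Canton S B, 2 between the insertion lines and 9 ribosomal protein genes. On linear Signal it called 106, 4, 3, 3, 3 and 7 in the same order. With only the groups compared, 1 was called between BG02257 and Canton S B, and 17 between BG02514 and Canton S B with another balance (14 higher and 3 lower, against 8 and 7). Without both BG02257 male arrays 146 were called between the sexes (121 higher and 25 lower in females). Both settings use fewer arrays. The GAPDH covariate gave 14 between BG02257 and Canton S B, 347 between the sexes (213 higher and 134 lower in females, against 164 and 74) and 25 ribosomal protein genes. With an estimated correlation camera called 0 lists in each of the 4 comparisons, and fry called 5, 1, 0 and 0 in one direction. Mixed fry called 16, 5, 1 and 6.

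Leaving out each array in turn gave 116 to 300 sex calls, 7 to 57 by line, 4 to 20 between BG02514 and Canton S B, 2 to 24 between BG02257 and Canton S B, 2 to 90 between the insertion lines, 0 to 9 for the interaction and 8 to 21 ribosomal protein genes. The lowest sex count came without BG02514 female 2. The highest counts for sex, line, BG02257 against Canton S B, the insertion lines and the interaction came without BG02257 male 1b. In that fit BG02257 males are represented by male 1a alone, the array with raised yolk protein Signals. No difference between sexes or lines was called in the 3'/5' ratios of 3 controls (12 exact permutation tests, smallest Benjamini-Hochberg adjusted p = 0.644). With 4 arrays per line, no single comparison of lines could pass the adjustment over 12 tests, so these tests decide little between lines. Genes of low Signal, Gr5a among them, are limited by signal over background.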

Other observations

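The genes here were chosen after their values were seen, so they describe single genes and no group of genes, and no explanation was tested for them. Lower in females were Gnmt, a glycine methyltransferase (−2.06 ± 0.40 on the log2 scale, SE, adjusted p = 0.0193), Cbs (−1.05), Ssadh (−0.88), P5CS (−0.60) and Got2 (−0.55). Higher in females were the ornithine decarboxylase gene Odc1 (1.54 ± 0.13, adjusted p = 9.57e-05), SpdS (0.75), Nop10 (1.92), Fib (0.84), eEF1gamma (0.60), Mlp84B (0.72) and Zasp66 (0.65). Gnmt and P5CS each lost their call in 5 of the 12 fits that left out 1 array, and the other genes just named in 0. Other genes chosen in the same way were called with all 12 arrays and also lost their call: gbb, between the insertion lines, in 12 fits, Pepck1, Ass and Scgdelta in 10, Mp20, svp and Imp in 9 and Rack1 in 3. The GAPDH 3'/5' ratio was highest in Canton S B female 1 (6.16) and Canton S B male 2 (5.89).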
